A study of Homo sapiens with 12 samples.

How the data were processed

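The study measured poly(A) RNA in 12 libraries of the human glioblastoma line U251: control or CD44 short hairpin RNA, each with DMSO or 50 µM temozolomide for 24 h, 3 libraries per group. The libraries were made with oligo-dT selection and sequenced on a NovaSeq instrument, per the labels. Groups were taken from the labels, and the columns marked NC with temozolomide were read as control hairpin. The labels do not say whether the 3 libraries of a group are separate cultures, so every p-value measures only the spread between these libraries. The authors' count table holds estimated counts per gene, with fractions in 10.7% to 12.0% of the values per library where reads were shared between genes. The deposited second table holds FPKM, fragments scaled to transcript length and library total. Per the submitters' processing notes, fastp 0.18.0, Bowtie2 2.2.8, HISAT2, StringTie 1.3.1 and RSEM were used, without the part each had. The genome build and annotation are not given in the sources used here. Locations come from a GRCh38 reference annotation joined by gene ID, which held 20257 of the 20289 IDs.

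Estimated counts were rounded and analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with its defaults (12821 of 20289, where 3153 had no count in any library), libraries were scaled by TMM, and 1 quasi-likelihood model with 4 group means was fitted to all 12 libraries. The biological coefficient of variation was 3.90%. Library totals, in units of 1e6, ran from 13.5 to 24.8, so a floor of 3 counts is 0.121 to 0.222 CPM. A gene was called at a Benjamini-Hochberg adjusted p below 0.05. The comparisons were knockdown under each treatment, temozolomide in each kind of cell, both changes against neither, and the difference between the temozolomide responses. SE values were derived from the log2 fold change and its F statistic. Gene lists, 43 in number and sharing genes, were written before the data were examined, and 41 had at least 5 tested genes. They were tested with limma 3.58.1 camera on log2 CPM (prior count 2, correlation between genes 0.01) with Benjamini-Hochberg adjustment over the lists, and again with the correlation estimated. Of 1467 listed symbols 1466 were found. Replicate numbers did not clearly pair libraries across groups, so no pairing was used. Libraries of the same number correlated at -0.077 to 0.14 over 18 pairs, and 6 of 12 libraries correlated best with their own number. This does not exclude a weak pairing.

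Before the data were examined, a rule fixed which genes could be named. It takes CD44, and the 8 largest called rises and falls per comparison of 2 groups with no overlap between groups. For the difference it takes the 5 largest each way, without the condition on overlap. These rises and falls need a mean of at least 5 CPM in the highest group. It also takes up to 2 members per direction with the smallest p in lists that shifted or had at least 5 called members. MGMT, CDKN1A, MSH6, SOX2, VIM and MKI67 are always included. The rule gives 730 gene results. The text describes only a part of the lists that shifted. The text names a part of them, from the lists it describes gene by gene. That part was picked after the values, and their calls under the alternatives, were seen, and genes whose call was lost under an alternative were passed over in several lists. The named genes therefore look steadier than the 730, all of which were carried through the alternatives that gave them an adjusted p.

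The alternatives fixed beforehand were relative log expression factors, library totals alone, DESeq2 1.42.0, no or a stricter low-count filter (at least 1 CPM in 3 libraries), only the groups compared, the replicate number as a block, each library left out in turn, limma fits to log2(FPKM + 1) and log2(FPKM + 0.1) and to unfiltered FPKM, other thresholds, and for lists an estimated correlation and limma's fry. Corrections for GC content, and for GC content with length, by splines with 5 degrees of freedom per library, were chosen after seeing the data. GC content and length were those of each gene's longest transcript in the reference annotation. Other splits of the libraries were refitted, at most 100 per comparison. The procedure was tested on simulated data with 66 or 67 genes planted at each size, none of them with a low mean count. At a log2 change of 0.25 it recovered 56.1% to 60.6% in comparisons of 2 groups and 34.8% in the difference. At 1 it recovered 100.0% and 94.0%, and 9 to 19 unchanged genes were called. The simulated genes varied independently of each other, and these shares do not cover tested genes with low counts. A shift planted in 1 of 41 lists was called with 0 other lists in limma camera. This check on simulated data does not show whether the preset correlation holds for the genes of the real libraries. There, for knockdown under DMSO, limma camera shifted 16 lists with the preset and 0 with an estimated correlation. Other splits of the libraries in comparisons of 2 groups, with at most 1 gene called, still shifted up to 20 lists with the preset. A planted GC trend gave 3628 edgeR calls among unchanged genes before and 0 after the GC correction. Figures were drawn in Python 3.11.15 with matplotlib 3.10.9.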

Results

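Poly(A) RNA was sequenced in 12 libraries of U251, an established human glioblastoma cell line, in 4 groups of 3. Cells carried a control short hairpin RNA or one against CD44, the cell-surface receptor for hyaluronan, and received 50 µM temozolomide, a DNA-alkylating drug given against glioblastoma, or its solvent DMSO for 24 h. The groups are called control DMSO, knockdown DMSO, control temozolomide and knockdown temozolomide, and the libraries of each are numbered 1 to 3. The total estimated count per library, in units of 1e6, was 15.7, 15.7 and 17.6 in control DMSO, 15.1, 16.5 and 19.8 in knockdown DMSO, 24.8, 16.4 and 16.9 in control temozolomide, and 16.1, 20.2 and 13.5 in knockdown temozolomide. Of the 20289 genes in the table, 12821 passed the filter on low counts. The first principal component held 41.6% of the variance and separated the 6 knockdown from the 6 control libraries, and the second held 15.6% and separated temozolomide from DMSO.

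Several measured limits apply to the values. Genes with a GC content above 60% stood above those under 40% in each control DMSO library, by 0.15, 0.07 and 0.22 in log2 units, and below them in each knockdown DMSO library, by -0.06, -0.03 and -0.08. In both temozolomide groups this difference took either sign, from -0.13 to 0.04 in the control and from -0.12 to 0.08 in the knockdown libraries. GBP1, GBP3, GBP5, ALPP, HLA-B, KRT14, RPS28, SAMD9 and PCDHB9 have close copies in the genome, and ASDURF, ANKHD1-EIF4EBP3 and MSANTD3-TMEFF1 overlap other genes, so their values are uncertain where reads could be shared. MGMT, which removes from DNA the alkyl group that temozolomide adds, had 0 counts in 11 libraries and 1 in knockdown temozolomide 2. A level of 3 counts would be 0.121 to 0.222 CPM (counts per 1e6), so MGMT was not detectable at this depth. This floor covers counting error only, while the SE and SD values in the text include the spread between libraries.

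CD44 (ENSG00000026508, chromosome 11, 35138870 to 35232402 on the plus strand in the GRCh38 reference annotation) had 17129, 16613 and 17749 counts in control DMSO and 6323, 6821 and 8244 in knockdown DMSO. It had 21216, 13354 and 13735 counts in control temozolomide and 5341, 6831 and 4639 in knockdown temozolomide. Group means were 1091 ± 43.3, 419.8 ± 1.03, 821 ± 25.8 and 326 ± 6.60 CPM (SD, n = 3), so that the knockdown groups held 38.5% and 29.9% and the control temozolomide group 75.3% of the control DMSO level. The knockdown changed CD44 by a log2 fold change of -1.38 (SE 0.03) under DMSO and -1.33 (SE 0.03) under temozolomide, with adjusted p = 3.2e-17 and 1.2e-16 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Temozolomide changed it by -0.41 in control and -0.36 in knockdown cells (adjusted p = 1.3e-08 and 1.3e-07, edgeR quasi-likelihood, Benjamini-Hochberg). The difference between these responses was 0.05 (SE 0.05), with adjusted p = 0.670 in the same edgeR test.

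**Figure D1:**
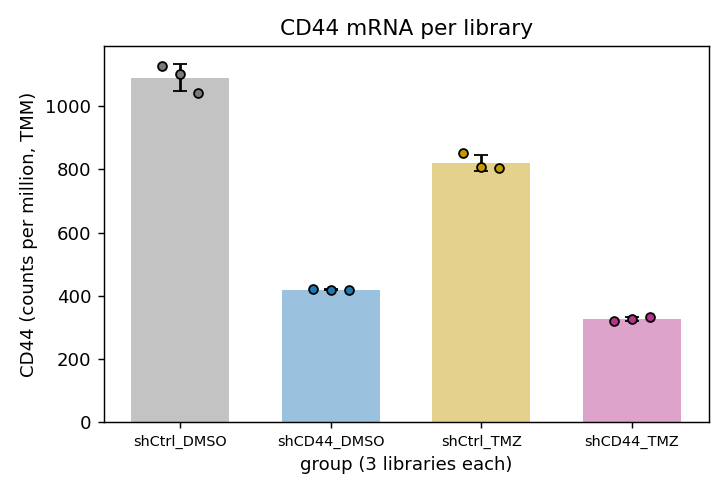
CD44 in CPM in each of the 12 libraries, by group, with group means and SD (n = 3). All 6 knockdown libraries lie below all 6 control libraries, with group means of 1091 and 821 CPM against 419.8 and 326 CPM.

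Knockdown against control cells under DMSO asks which RNAs differ when less CD44 is made and no drug is present. Interferon-stimulated genes rose: all 42 tested members of that list passed the threshold over all genes, and 42 adjusted over the list alone, with a median log2 fold change of 1.28 (interquartile range 0.87 to 2.08). The antiviral GTPase GBP1 went from 5.20 ± 0.52 to 35.7 ± 1.35 CPM, the RNA helicase DDX60 from 9.97 ± 1.02 to 31.4 ± 1.34 CPM, and OAS2, which senses double-stranded RNA, from 1.82 ± 0.09 to 17.3 ± 0.64 CPM (SD, n = 3). RSAD2, which blocks viral replication, had the highest log2 fold change of the named genes, 3.46 (SE 0.43). In limma camera with Benjamini-Hochberg adjustment the list had adjusted p = 1.6e-17, and adjusted p = 0.220 with an estimated correlation. Among NF-kB targets and cytokines 19 of 24 rose and 1 fell (20 and 1 adjusted over the list alone), with a median of 1.02 and camera adjusted p = 9.8e-07 (limma), or adjusted p = 0.18 with an estimated correlation. TRAF1, an adaptor of tumour necrosis factor receptors, rose by 2.83 (SE 0.22), the apoptosis inhibitor BIRC3 by 1.43 (SE 0.11) and the superoxide dismutase SOD2 by 0.70 (SE 0.04), while TNFAIP2 fell by 0.86 (SE 0.04). Of 19 antigen presentation genes 13 rose and 2 fell, the same numbers adjusted over the list alone (median 0.30, limma camera adjusted p = 0.000499, adjusted p = 0.220 with an estimated correlation). They include the class I molecule HLA-B at 0.79 (SE 0.04) and the peptide-trimming enzyme ERAP2 at 0.73 (SE 0.06). Every gene value in this paragraph had adjusted p of 1.4e-06 or less in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

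Lists of YAP and TAZ targets, growth factor response, integrins, epithelial-mesenchymal transition and proteolysis rose as well in knockdown cells under DMSO. Collagen and matrix genes did not shift, with 18 rises and 16 falls among 47 (18 and 17 adjusted over the list alone, median 0.07, limma camera adjusted p = 0.659), nor did hyaluronan and CD44 partner genes, with 10 and 5 among 24 (10 and 6 adjusted over the list alone, median 0.05, limma camera adjusted p = 0.546), although limma's fry called this second list. Among YAP and TAZ targets 19 of 28 rose and 3 fell, the same numbers adjusted over the list alone, with a median of 0.31 (limma camera adjusted p = 1.9e-06, adjusted p = 0.18 with an estimated correlation). CCN1, a matrix-bound growth regulator, rose by 1.34 (SE 0.04) and NT5E, the enzyme CD73, by 2.00 (SE 0.09), while the small GTPase RND3 fell by 0.45 (SE 0.04). Of 39 growth factor and MAPK response genes 25 rose and 8 fell (27 and 8 adjusted over the list alone, median 0.37, limma camera adjusted p = 0.000350, adjusted p = 0.220 with an estimated correlation). The receptor kinase AXL rose by 1.16 (SE 0.05), the transcription factor ETV5 rose from 62.3 ± 3.33 to 112 ± 1.68 CPM, and the receptor PDGFRA fell from 349 ± 9.57 to 194 ± 6.41 CPM (SD, n = 3). Integrin and focal adhesion genes rose in 15 and fell in 3 of 34 cases (16 and 3 adjusted over the list alone, median 0.13, limma camera adjusted p = 0.000653, adjusted p = 0.266 with an estimated correlation). ITGA2 and ITGB1, which pair as a collagen receptor, rose by 0.70 (SE 0.05) and 0.47 (SE 0.03), and talin TLN1, which links integrins to actin, fell by 0.59 (SE 0.03). The integrin median was 0.21 with a correction for GC content. For epithelial-mesenchymal transition genes, 12 of 22 rose and 5 fell (13 and 5 adjusted over the list alone, median 0.18, limma camera adjusted p = 0.0161, adjusted p = 0.220 with an estimated correlation). The call was lost with a correction for GC content and length (median 0.17), and the median was 0.30 without control DMSO 3. CCN2, a TGFβ-induced matrix protein, rose by 1.47 (SE 0.08), and the matrix protein POSTN fell by 0.50 (SE 0.04). Of 31 metalloproteinase and proteolysis genes 16 rose and 5 fell (16 and 6 adjusted over the list alone, median 0.15, limma camera adjusted p = 0.0341, adjusted p = 0.380 with an estimated correlation). This call was lost when libraries were scaled by their totals alone (median 0.19), without control DMSO 3 (0.15) and without knockdown DMSO 1 (0.13). The sheddase ADAM19 rose by 1.74 (SE 0.06) and the lysosomal protease CTSB by 1.13 (SE 0.03), and the inhibitor TIMP2 fell by 0.44 (SE 0.03). All genes named in this paragraph had adjusted p of 2.5e-08 or less (edgeR quasi-likelihood, Benjamini-Hochberg).

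Smaller rises were found for mitosis genes. In the G2/M list 24 of 54 genes rose and 4 fell (27 and 5 adjusted over the list alone), with a median of 0.10 that became 0.06 with a correction for GC content (limma camera adjusted p = 0.00151, adjusted p = 0.380 with an estimated correlation). The spindle protein CKAP2L rose by 0.33 (SE 0.04) and cyclin CCNA2 fell by 0.17 (SE 0.03), with edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 7.4e-07 and 0.000284. MKI67, a marker of dividing cells, fell by 0.12 (SE 0.03, edgeR adjusted p = 0.00676), a call that was lost with library totals alone, in the fits to FPKM, without control DMSO 2 (-0.08) and without knockdown DMSO 1 (-0.09).

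Ribosomal protein genes fell in knockdown cells under DMSO: all 72 passed the threshold, and 72 adjusted over the list alone, with a median log2 fold change of -0.36 (interquartile range -0.43 to -0.32). RPS28 went from 119 ± 19.0 to 52.5 ± 2.36 CPM and RPS4X from 904 ± 51.0 to 658 ± 18.9 CPM (SD, n = 3), and the list had limma camera adjusted p = 1.6e-17, with adjusted p = 0.356 with an estimated correlation. Scaling by library totals alone gave 0 rises and 71 falls with a median of -0.32. Of 52 nuclear genes of oxidative phosphorylation 37 fell and 0 rose (40 and 0 adjusted over the list alone), with a median of -0.20, which was -0.13 without control DMSO 3 (limma camera adjusted p = 7.5e-08, adjusted p = 0.356 with an estimated correlation). The ATP synthase subunits ATP5F1A and ATP5F1B fell by 0.34 (SE 0.03) and 0.29 (SE 0.03). Mitochondrially encoded genes, 8 falls among 13, had a median of -0.18 (8 adjusted over the list alone, limma camera adjusted p = 0.0143, adjusted p = 0.429 with an estimated correlation). That call was lost with a correction for GC content and length (-0.08) and without knockdown DMSO 1 (-0.16). Hypoxia and glycolysis genes fell in 23 and rose in 3 of 35 cases, the same numbers adjusted over the list alone (median -0.19, limma camera adjusted p = 5.8e-05, adjusted p = 0.18 with an estimated correlation). The hypoxia-induced NDRG1 fell by 1.06 (SE 0.05) and the aldolase ALDOC by 1.36 (SE 0.12), and the enolase ENO2 rose by 0.41 (SE 0.06). Of 26 cholesterol synthesis genes 12 fell and 2 rose, the same numbers adjusted over the list alone (median -0.15, limma camera adjusted p = 0.0104, adjusted p = 0.18 with an estimated correlation). Of the members of this list, the fatty acid desaturase SCD and the reductase DHCR7 fell by 0.50 (SE 0.03) and 0.49 (SE 0.04). Of 10 epithelial markers 6 fell and 1 rose, the same numbers adjusted over the list alone (median -0.51, limma camera adjusted p = 0.00653, adjusted p = 0.220 with an estimated correlation). Of 6 neuron markers 4 rose and 0 fell, the same numbers adjusted over the list alone (median 0.70, limma camera adjusted p = 0.0479, adjusted p = 0.220 with an estimated correlation). That call was lost with library totals alone (0.74), with the replicate number as a block (0.70), and without control DMSO 2 (0.68), control DMSO 3 (0.75) or knockdown DMSO 1 (0.66). The keratin KRT14 fell from 259 ± 10.5 to 106 ± 6.33 CPM and the transcription factor ELF3 from 77.9 ± 3.40 to 35.1 ± 0.36 CPM (SD, n = 3). In this paragraph every gene had adjusted p of 3.9e-06 or less (edgeR quasi-likelihood, Benjamini-Hochberg).

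Over all genes, 2710 rose and 2748 fell with knockdown under DMSO, of which 338 and 120 changed at least 2-fold. Scaling by library totals alone gave 3387 rises and 2167 falls, and a correction for GC content, chosen after the results were seen and made over the 12782 genes with a GC value, gave 2604 and 2921, with 850 of 5451 calls lost. Large rises outside the lists were those of the immune checkpoint ligand PDCD1LG2 at 3.16 (SE 0.31), the matrix protein LRRC17 at 2.75 (SE 0.24), the GTPase GBP5 at 2.73 (SE 0.23) and the cytoskeletal protein NAV3 at 2.68 (SE 0.24). The falls with the largest fold were those of the phosphatase ALPP at -2.46 (SE 0.19), the diamine oxidase AOC1 at -2.16 (SE 0.05), TMEM100 at -1.84 (SE 0.22) and UPK3B at -1.75 (SE 0.18), all with adjusted p of 7.6e-07 or less (edgeR quasi-likelihood, Benjamini-Hochberg). The stemness factor SOX2 fell by 0.42 (SE 0.03), the mismatch repair gene MSH6 fell by 0.21 (SE 0.03) and vimentin VIM rose by 0.19 (SE 0.03), with edgeR adjusted p = 4.2e-09, 2.7e-05 and 6.1e-05. CDKN1A, a cell cycle inhibitor induced by p53, had a log2 fold change of 0.01 (SE 0.06, edgeR adjusted p = 0.908), and of -0.03 without knockdown DMSO 1.

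Knockdown against control cells under temozolomide asks the same of cells that received the drug. Ribosomal protein genes fell in 71 of 72 cases, 71 adjusted over the list alone, with a median of -0.40 (interquartile range -0.49 to -0.33, limma camera adjusted p = 9.4e-21, adjusted p = 0.346 with an estimated correlation). RPL14 fell from 761 ± 18.7 to 485 ± 40.3 CPM and RPS28 from 103 ± 5.37 to 52.2 ± 3.43 CPM (SD, n = 3). Interferon-stimulated genes rose in 38 of 42 cases, 38 adjusted over the list alone, with a median of 0.85 (interquartile range 0.47 to 1.20, limma camera adjusted p = 1.1e-08, adjusted p = 0.380 with an estimated correlation). Without knockdown temozolomide 1 this median was 0.51. GBP1 rose by 2.07 (SE 0.14) and the transcription factor IRF1 by 0.97 (SE 0.11). Of 52 oxidative phosphorylation genes 39 fell (43 adjusted over the list alone, median -0.22, limma camera adjusted p = 6.2e-09, adjusted p = 0.346 with an estimated correlation), among them the succinate dehydrogenase subunit SDHD at -0.40 (SE 0.05). Hypoxia genes fell in 18 and rose in 4 of 35 cases, the same numbers adjusted over the list alone (median -0.14, limma camera adjusted p = 0.000546, adjusted p = 0.242 with an estimated correlation), with NDRG1 at -1.11 (SE 0.05). Cholesterol synthesis genes fell in 14 and rose in 1 of 26 cases (16 and 1 adjusted over the list alone, median -0.16, limma camera adjusted p = 0.000986, adjusted p = 0.221 with an estimated correlation), with SREBF2, the pathway's transcription factor, at -0.44 (SE 0.04). Epithelial markers fell in 6 and rose in 2 of 10 cases, also adjusted over the list alone (median -0.43, limma camera adjusted p = 0.00675, adjusted p = 0.330 with an estimated correlation), with KRT14 at -1.64 (SE 0.05). Each named gene here had adjusted p of 7.0e-07 or less (edgeR quasi-likelihood, Benjamini-Hochberg).

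NF-kB targets rose in 17 of 24 cases under temozolomide and 1 fell (17 and 3 adjusted over the list alone, median 0.77, limma camera adjusted p = 4.0e-05, adjusted p = 0.242 with an estimated correlation). TRAF1 rose by 2.73 (SE 0.22) and the ubiquitin-editing enzyme TNFAIP3 by 1.22 (SE 0.10). YAP and TAZ targets rose in 19 and fell in 2 of 28 cases (19 and 3 adjusted over the list alone, median 0.39, limma camera adjusted p = 1.4e-05, adjusted p = 0.242 with an estimated correlation). MAPK response genes rose in 26 and fell in 5 of 39 cases (26 and 6 adjusted over the list alone, median 0.43, limma camera adjusted p = 3.2e-05, adjusted p = 0.242 with an estimated correlation). AXL rose by 1.36 (SE 0.05) and ETV5 by 0.98 (SE 0.05). Integrin and focal adhesion genes rose in 19 and fell in 5 of 34 cases, also adjusted over the list alone (median 0.20, limma camera adjusted p = 0.000481, adjusted p = 0.335 with an estimated correlation), with the actin-binding proteins ACTN1 at 0.58 (SE 0.04) and ZYX at 0.65 (SE 0.05). G2/M genes rose in 29 and fell in 5 of 54 cases, also adjusted over the list alone (median 0.13, limma camera adjusted p = 0.00263, adjusted p = 0.429 with an estimated correlation), with the mitotic kinase PLK1 at 0.34 (SE 0.04). Mesenchymal glioblastoma genes rose in 17 and fell in 8 of 33 cases (18 and 8 adjusted over the list alone, median 0.11, limma camera adjusted p = 0.0319, adjusted p = 0.429 with an estimated correlation), a call lost without control temozolomide 3 (median 0.10). The matrix cross-linking enzyme LOX fell from 32.6 ± 2.11 to 17.9 ± 1.97 CPM (SD, n = 3). All genes named in this paragraph had adjusted p of 7.7e-07 or less (edgeR quasi-likelihood, Benjamini-Hochberg).

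In all, 2823 genes rose and 2603 fell with knockdown under temozolomide, and 427 of them changed at least 2-fold. Library totals alone gave 3457 rises and 2126 falls, and a correction for GC content gave 2983 and 2698, with 165 of 5419 calls lost. Genes with large rises include NAV3 at 2.85 (SE 0.24), the G protein regulator RGS4 at 2.81 (SE 0.26), DMBT1 at 2.47 (SE 0.19) and GBP3 at 2.36 (SE 0.13). The protease PRSS35 fell by 2.11 (SE 0.07), AOC1 by 2.06 (SE 0.05), the neurotrophin receptor NTRK3 by 2.04 (SE 0.19) and the epithelial transcription factor EHF by 1.76 (SE 0.07), each with adjusted p of 2.1e-08 or less (edgeR quasi-likelihood, Benjamini-Hochberg). SOX2 fell by 0.54 (SE 0.03), MSH6 fell by 0.26 (SE 0.03) and VIM rose by 0.32 (SE 0.03), with edgeR adjusted p = 7.7e-11, 2.2e-06 and 4.9e-08. MKI67, at -0.03 (SE 0.03), and CDKN1A, at 0.12 (SE 0.06), did not pass (edgeR adjusted p = 0.473 and 0.113). The sign of MKI67 turned with library totals alone (0.00526) and in the fits to FPKM (0.00240).

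**Figure D2:**
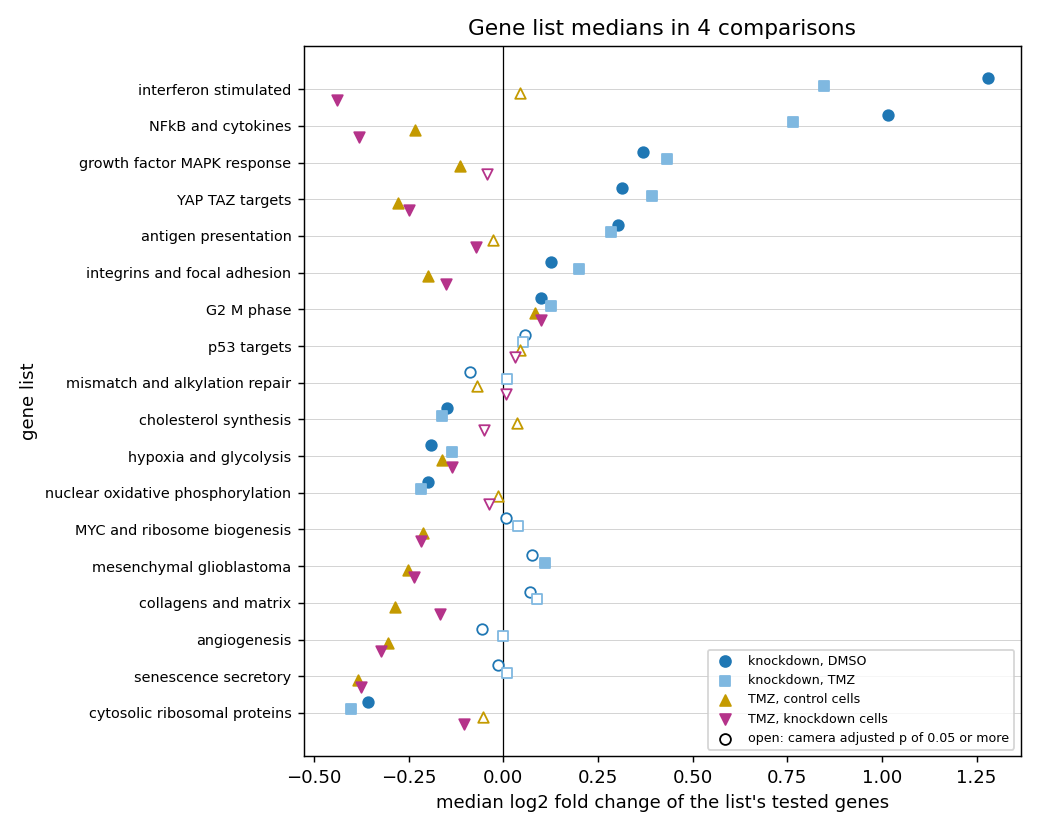
Median log2 fold change of 18 gene lists (horizontal position) in the 4 comparisons that change 1 factor. Under DMSO, knockdown gave medians of 1.28 for interferon-stimulated and -0.36 for ribosomal protein genes, and temozolomide in control cells gave -0.25 for mesenchymal glioblastoma genes.

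The knockdown effects under DMSO and under temozolomide come from separate libraries, so they can be set side by side. Both compare the same hairpins, so an effect of the hairpin itself would recur in both. Their agreement therefore does not separate it from an effect of less CD44. Across the 12821 genes, which are not independent replicates, Pearson's r of the log2 fold changes was 0.68 (jackknife SE 0.0441 over libraries) and Spearman's rho 0.73. Both comparisons called 3746 genes, 1917 of which rose in both, 1809 fell in both and 20 went opposite ways, where independent lists would share 597 and 558. Of the genes called under DMSO, such as AOC1 and NAV3, 93.1% had the same sign under temozolomide. The correlation was 0.26 without the low-count filter and 0.32 in DESeq2, which kept low genes.

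**Figure D3:**
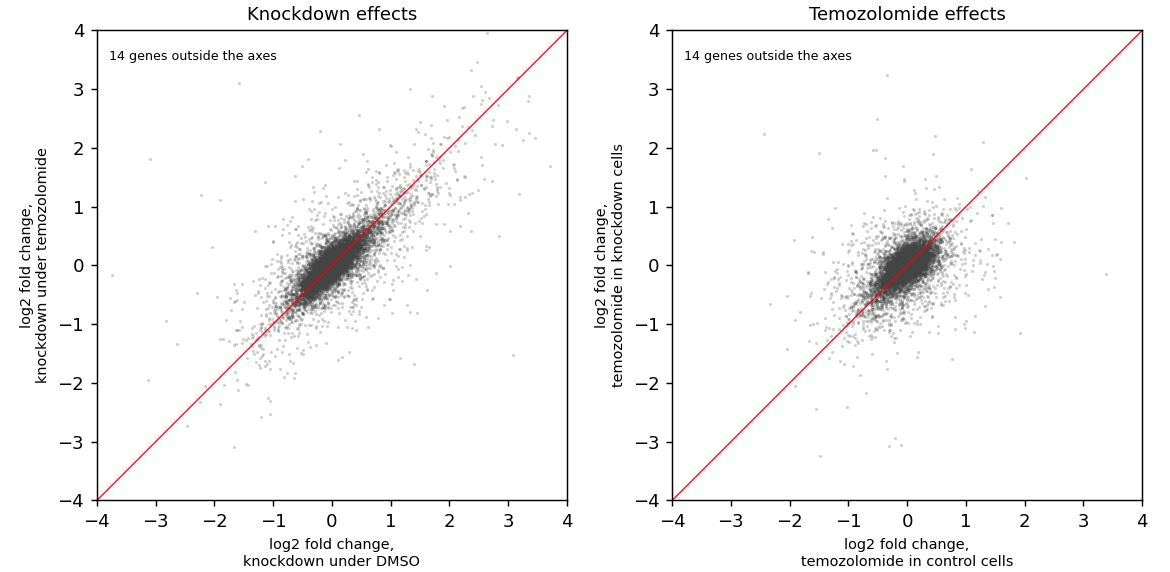
Log2 fold changes of all tested genes, knockdown under temozolomide against knockdown under DMSO and temozolomide in knockdown against control cells, with axes from -4 to 4 and 14 genes outside each plot. Pearson's r across genes is 0.68 for the knockdown and 0.37 for temozolomide.

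Temozolomide against DMSO in control cells asks how the line responds to the drug at 24 h. Mesenchymal glioblastoma genes fell in 23 of 33 cases and none rose (25 and 0 adjusted over the list alone), with a median log2 fold change of -0.25 (interquartile range -0.51 to -0.15, limma camera adjusted p = 1.8e-11, adjusted p = 0.0540 with an estimated correlation). The matrix protein TNC went from 1879 ± 64.6 to 1224 ± 47.4 CPM and the collagen chain COL1A2 from 208 ± 3.06 to 109 ± 7.08 CPM (SD, n = 3). Genes of MYC activity and ribosome biogenesis fell in 27 of 35 cases (28 adjusted over the list alone, median -0.21, limma camera adjusted p = 1.8e-11, adjusted p = 0.0540 with an estimated correlation), among them the ribosome assembly factors BOP1 at -0.41 (SE 0.05) and FBL at -0.31 (SE 0.04). Angiogenesis genes fell in 20 of 28 cases, 20 adjusted over the list alone (median -0.31, limma camera adjusted p = 1.9e-08), and this list kept its call with an estimated correlation (adjusted p = 0.0308). The growth factor VEGFA fell by 0.48 (SE 0.04) and THBS1, which inhibits vessel growth, by 0.83 (SE 0.04). Collagen and matrix genes fell in 24 and rose in 2 of 47 cases (25 and 3 adjusted over the list alone, median -0.29, limma camera adjusted p = 2.6e-08, adjusted p = 0.0676 with an estimated correlation). YAP and TAZ targets fell in 16 of 28 cases (17 adjusted over the list alone, median -0.28, limma camera adjusted p = 3.5e-08, adjusted p = 0.0540 with an estimated correlation), and senescence secretory genes in 13 of 22, also adjusted over the list alone (median -0.38, limma camera adjusted p = 1.1e-06, adjusted p = 0.0540 with an estimated correlation). The repair-linked membrane protein MYOF fell by 0.44 (SE 0.03), and the growth factor-binding proteins IGFBP5 and IGFBP4 fell by 0.84 (SE 0.04) and 0.44 (SE 0.03). In this paragraph every gene had adjusted p of 2.1e-06 or less (edgeR quasi-likelihood, Benjamini-Hochberg).

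Further lists fell with temozolomide in control cells. Hypoxia and glycolysis genes fell in 17 and rose in 2 of 35 cases (19 and 2 adjusted over the list alone, median -0.16, limma camera adjusted p = 1.1e-05, adjusted p = 0.0654 with an estimated correlation), with the glucose transporter SLC2A1 at -0.47 (SE 0.03) and the enolase ENO1 at -0.40 (SE 0.03). Integrin and focal adhesion genes fell in 19 and rose in 1 of 34 cases (19 and 2 adjusted over the list alone, median -0.20, limma camera adjusted p = 1.6e-05, adjusted p = 0.158 with an estimated correlation), with the caveola protein CAV1 at -0.61 (SE 0.04) and ITGB4 at -0.57 (SE 0.03). Epithelial markers fell in 7 of 10 cases (8 adjusted over the list alone, median -0.45, limma camera adjusted p = 0.000339, adjusted p = 0.0897 with an estimated correlation), with KRT5 at -0.55 (SE 0.05) and ELF3 at -0.73 (SE 0.05). Hyaluronan and CD44 partner genes fell in 14 and rose in 4 of 24 cases, also adjusted over the list alone (median -0.21, limma camera adjusted p = 0.000393, adjusted p = 0.158 with an estimated correlation), with the proteoglycan VCAN at -0.60 (SE 0.04) and the hyaluronan receptor LAYN at -0.53 (SE 0.04). TGFβ targets fell in 15 and rose in 3 of 29 cases (15 and 4 adjusted over the list alone, median -0.22, limma camera adjusted p = 0.00252, adjusted p = 0.115 with an estimated correlation), with TGFBI at -0.63 (SE 0.04) and PMEPA1 at -0.58 (SE 0.04). Only the G2/M list shifted up: 22 of 54 genes rose and 0 fell (24 and 3 adjusted over the list alone, median 0.08, limma camera adjusted p = 0.000210, adjusted p = 0.279 with an estimated correlation), with CKAP2L at 0.29 (SE 0.04). With library totals alone, the medians were -0.09 for hypoxia, -0.13 for integrin and 0.15 for G2/M genes, and corrections for GC content and for GC content with length gave 0.05 for G2/M genes. Rises and falls were 4 and 15 for integrin genes with library totals alone, and 12 and 3 for G2/M genes with the correction for GC content. Each named gene here had adjusted p of 1.2e-05 or less (edgeR quasi-likelihood, Benjamini-Hochberg).

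p53 targets did not shift as a list with temozolomide in control cells: 7 of 35 rose and 2 fell, also adjusted over the list alone (median 0.05, limma camera adjusted p = 0.355), and with library totals alone 12 rose and 2 fell with a median of 0.11. The median was 0.01 with a correction for GC content and -0.0027 with one for GC content and length. RRM2B, which supplies nucleotides for repair, rose by 0.36 (SE 0.04) and the stress protein TP53INP1 by 0.52 (SE 0.06), while the kinase PLK2 fell by 0.51 (SE 0.03), with edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 1.3e-06, 2.4e-06 and 1.0e-09. RRM2B was at 0.24 with a correction for GC content and 0.23 with one for GC content and length. CDKN1A, at 0.07 (SE 0.06), SOX2, at 0.03 (SE 0.03), MSH6, at 0.07 (SE 0.03), and MKI67, at -0.07 (SE 0.03), did not pass (edgeR adjusted p = 0.400, 0.514, 0.155 and 0.109). Correcting for GC content turned the sign of MSH6 (-0.00165). VIM fell by 0.42 (SE 0.03, edgeR adjusted p = 3.2e-09).

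In all, 1505 genes rose and 2024 fell with temozolomide in control cells, 30 and 61 of them at least 2-fold. Scaling by library totals alone gave 2870 rises and 1295 falls, so the balance of rises and falls depends on the scaling. The log2 fold changes correlated with GC content across genes (Spearman's rho -0.33), and a correction for it gave 1136 rises and 2001 falls, with 1033 of 3522 calls lost and 21 of those 3522 turned in sign. The membrane-shaping protein REEP1 rose by 1.19 (SE 0.15), the reductase DHRS2 by 0.78 (SE 0.07) and CSRNP3 by 0.76 (SE 0.15). C1orf116 fell by 1.83 (SE 0.15), the interleukin receptor IL7R by 1.67 (SE 0.07), the nitric oxide synthase NOS2 by 1.46 (SE 0.10) and the chemokine CCL2 by 1.27 (SE 0.11), each with adjusted p of 0.000623 or less (edgeR quasi-likelihood, Benjamini-Hochberg).

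Temozolomide against DMSO in knockdown cells asks how cells with less CD44 respond to the drug. Angiogenesis genes fell in 17 of 28 cases (20 adjusted over the list alone, median -0.32, limma camera adjusted p = 9.1e-11) and genes of MYC activity and ribosome biogenesis in 24 of 35 (29 adjusted over the list alone, median -0.22, limma camera adjusted p = 2.7e-11). YAP and TAZ targets fell in 16 of 28 cases (18 adjusted over the list alone, median -0.25, limma camera adjusted p = 1.0e-09), and epithelial-mesenchymal transition genes fell in 15 and rose in 1 of 22 (18 and 1 adjusted over the list alone, median -0.25, limma camera adjusted p = 8.9e-08). These 4 lists kept their calls with an estimated correlation, at adjusted p = 0.0129, 0.0399, 0.0439 and 0.0219. The clotting factor receptor F3 fell from 94.2 ± 5.36 to 50.0 ± 4.45 CPM, THBS1 from 473 ± 2.33 to 256 ± 14.5 CPM and POSTN from 145 ± 4.94 to 82.1 ± 2.90 CPM (SD, n = 3). The nucleolar protein NPM1 fell by 0.27 (SE 0.03) and the purine synthesis enzyme PAICS by 0.24 (SE 0.03). Interferon-stimulated genes fell in 24 of 42 cases (32 adjusted over the list alone), with a median of -0.44 (interquartile range -0.83 to -0.27, limma camera adjusted p = 9.0e-09, adjusted p = 0.307 with an estimated correlation). This median was -0.73 without knockdown temozolomide 1, -0.30 without knockdown temozolomide 2 and -0.38 without knockdown temozolomide 3. Against the control DMSO mean, the list median in knockdown temozolomide 1 was 1.23, within the 1.18 to 1.33 of the knockdown DMSO libraries. GBP1 fell by 0.86 (SE 0.11) and the antiviral ligase TRIM22 by 1.16 (SE 0.15). NF-kB targets fell in 9 of 24 cases (12 adjusted over the list alone, median -0.38, limma camera adjusted p = 2.1e-06, adjusted p = 0.0611 with an estimated correlation), with CCL2 at -1.46 (SE 0.10). All genes named in this paragraph had adjusted p of 1.1e-05 or less (edgeR quasi-likelihood, Benjamini-Hochberg).

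Mesenchymal glioblastoma genes fell in 18 of 33 cases in knockdown cells (19 fell and 1 rose adjusted over the list alone, median -0.24, limma camera adjusted p = 9.3e-09, adjusted p = 0.0611 with an estimated correlation). Collagen and matrix genes fell in 24 and rose in 1 of 47 cases (26 and 1 adjusted over the list alone, median -0.17, limma camera adjusted p = 2.4e-09, adjusted p = 0.0611 with an estimated correlation), and COL1A2 fell by 0.98 (SE 0.05). Epithelial markers fell in 6 of 10 cases (7 adjusted over the list alone, median -0.34, limma camera adjusted p = 4.1e-05, adjusted p = 0.0611 with an estimated correlation), with KRT5 at -0.85 (SE 0.05). Ribosomal protein genes had a median of -0.10 with 13 falls among 72 (9 adjusted over the list alone, limma camera adjusted p = 7.5e-05, adjusted p = 0.603 with an estimated correlation), which was -0.06 without knockdown DMSO 1. With library totals alone 0 of the 72 passed in edgeR (5 of them had an unadjusted p below 0.05), and the list call was lost in limma's fry. G2/M genes shifted up, with 19 rises and 3 falls among 54 (27 and 3 adjusted over the list alone, median 0.10, limma camera adjusted p = 6.7e-06, adjusted p = 0.215 with an estimated correlation), and the checkpoint kinase BUB1 rose by 0.23 (SE 0.04). With library totals alone the medians were -0.10 for collagen, -0.04 for ribosomal protein and 0.16 for G2/M genes, the last with 36 rises and 0 falls. Genes of double-strand break and crosslink repair shifted up with 9 rises and 5 falls among 50 (11 and 5 adjusted over the list alone, median 0.07, limma camera adjusted p = 0.0366, adjusted p = 0.309 with an estimated correlation), or 17 and 0 with library totals alone (median 0.13). That call was lost without knockdown DMSO 1 (0.06), knockdown DMSO 2 (0.04) or knockdown temozolomide 3 (0.05). The p53 target list did not shift (7 rises and 4 falls among 35, median 0.03, limma camera adjusted p = 0.302), and with library totals alone it had 16 rises and 2 falls with a median of 0.09, against medians of 0.04 and 0.06 with the corrections for GC content and for GC content with length. RRM2B rose by 0.22 (SE 0.04) and PLK2 fell by 0.55 (SE 0.03). In this paragraph every gene had adjusted p of 0.000437 or less (edgeR quasi-likelihood, Benjamini-Hochberg).

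In all, 1160 genes rose and 1694 fell with temozolomide in knockdown cells, 15 and 57 of them at least 2-fold. Library totals alone gave 2533 rises and 1078 falls, DESeq2 gave 676 and 1515, and a correction for GC content gave 1406 and 1819, with 82 of 2853 calls lost. REEP1 rose by 0.90 (SE 0.13), the microtubule protein MAP1A by 0.89 (SE 0.14) and the immediate-early factor EGR1 by 0.85 (SE 0.14). The kynurenine enzyme KMO fell by 2.05 (SE 0.16), the protease inhibitor PI15 by 1.87 (SE 0.14), IGFBP5 by 1.31 (SE 0.04) and IL7R by 1.28 (SE 0.07), each with adjusted p of 0.000207 or less (edgeR quasi-likelihood, Benjamini-Hochberg). VIM fell by 0.29 (SE 0.03, edgeR adjusted p = 8.5e-07). CDKN1A rose by 0.18 (SE 0.06, edgeR adjusted p = 0.0342), a call lost in DESeq2, without the low-count filter, and without knockdown DMSO 2 (0.16), knockdown DMSO 3 (0.15), knockdown temozolomide 1 (0.16) or knockdown temozolomide 3 (0.17). SOX2, at -0.09 (SE 0.03), MSH6, at 0.02 (SE 0.03), and MKI67, at 0.01 (SE 0.03), did not pass (edgeR adjusted p = 0.0724, 0.714 and 0.827), and MKI67 was at -0.02 without knockdown DMSO 1.

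The temozolomide effects in control and in knockdown cells share no library. Pearson's r of the log2 fold changes across the 12821 genes was 0.37 (jackknife SE 0.0664) and Spearman's rho 0.52. Both comparisons called 1642 genes, of which 522 rose in both, 1099 fell in both and 21 went opposite ways, where independent lists would share 136 and 267. Of the genes called in control cells, such as REEP1 and IL7R, 87.3% had the same sign in knockdown cells. The correlation was 0.09 without the low-count filter and 0.12 in DESeq2, and 0.51 to 0.56 in the fits to FPKM.

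Knockdown with temozolomide against neither asks what both changes do together. Ribosomal protein genes fell in 72 of 72 cases, 72 adjusted over the list alone (median -0.46, limma camera adjusted p = 3.4e-19, adjusted p = 0.410 with an estimated correlation), with RPL3 at -0.50 (SE 0.03). Hypoxia and glycolysis genes fell in 26 and rose in 3 of 35 cases (27 and 3 adjusted over the list alone, median -0.35, limma camera adjusted p = 7.1e-08, adjusted p = 0.187 with an estimated correlation). NDRG1 went from 188 ± 5.95 to 62.4 ± 2.48 CPM and the glycolysis regulator PFKFB3 from 175 ± 1.27 to 111 ± 4.57 CPM (SD, n = 3). Oxidative phosphorylation genes fell in 38 of 52 cases (40 adjusted over the list alone, median -0.28, limma camera adjusted p = 7.1e-08, adjusted p = 0.410 with an estimated correlation), with ATP5F1A at -0.42 (SE 0.03) and a list median of -0.18 without control DMSO 3. Genes of MYC activity fell in 25 and rose in 2 of 35 cases, also adjusted over the list alone (median -0.19, limma camera adjusted p = 5.2e-05, adjusted p = 0.187 with an estimated correlation), with FBL at -0.60 (SE 0.04). Epithelial markers fell in 8 and rose in 1 of 10 cases, also adjusted over the list alone (median -1.05, limma camera adjusted p = 0.000370, adjusted p = 0.187 with an estimated correlation), with KRT14 at -2.05 (SE 0.05) and ELF3 at -1.89 (SE 0.06). Interferon-stimulated genes rose in 37 of 42 cases, 37 adjusted over the list alone (median 0.84, limma camera adjusted p = 7.1e-08, adjusted p = 0.410 with an estimated correlation), with GBP1 at 1.91 (SE 0.14). G2/M genes rose in 39 and fell in 6 of 54 cases (39 and 7 adjusted over the list alone, median 0.21, limma camera adjusted p = 4.9e-06, adjusted p = 0.410 with an estimated correlation), with CKAP2L at 0.56 (SE 0.04). Of 6 neuron markers 4 rose and 0 fell, also adjusted over the list alone (median 0.86, limma camera adjusted p = 0.0392, adjusted p = 0.187 with an estimated correlation), a call lost with library totals alone (0.96) and without control DMSO 2 (0.84). Each named gene here had adjusted p of 1.8e-09 or less (edgeR quasi-likelihood, Benjamini-Hochberg).

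In all, 3255 genes rose and 3143 fell with both changes, 312 and 260 of them at least 2-fold. Library totals alone moved the median of all genes by 0.10 and gave 5053 rises and 2039 falls, with medians of -0.17 for oxidative phosphorylation and -0.09 for MYC activity. Rises and falls were then 5 and 17 for MYC activity and 42 and 1 for G2/M genes. A correction for GC content gave 3266 and 3292, with 570 of 6394 calls lost. CD44 was at -1.74 (SE 0.03), PDGFRA at -1.70 (SE 0.04) and the microfibril protein FBN2 at -1.79 (SE 0.04). ALPP fell by 3.66 (SE 0.22), NTRK3 by 3.10 (SE 0.17), TMEM100 by 2.78 (SE 0.24) and the vasoconstrictor EDN2 by 2.76 (SE 0.29), while NAV3 rose by 2.64 (SE 0.25), TRAF1 by 2.56 (SE 0.23) and the actin-binding CORO2B by 2.46 (SE 0.25), each with adjusted p of 1.0e-07 or less (edgeR quasi-likelihood, Benjamini-Hochberg). SOX2 fell by 0.50 (SE 0.03) and MSH6 by 0.19 (SE 0.03), with edgeR adjusted p = 1.2e-10 and 6.3e-05. The MSH6 call was lost in the fits to FPKM and its value was -0.09 with library totals alone. VIM fell by 0.10 (SE 0.03, edgeR adjusted p = 0.00992), but its value was 0.00109 with library totals alone and 0.00138 in the fits to FPKM, and the call was lost without control DMSO 1 (-0.08) or knockdown temozolomide 2 (-0.08). MKI67 fell by 0.10 (SE 0.03, edgeR adjusted p = 0.0122), a call lost with library totals alone, in the fits to FPKM, and without control DMSO 2 (-0.08) or knockdown temozolomide 1 (-0.08). CDKN1A rose by 0.19 (SE 0.06, edgeR adjusted p = 0.0121), a call lost in DESeq2 and without knockdown temozolomide 1 (0.17), and was at 0.30 with library totals alone.

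The difference between the temozolomide responses of knockdown and control cells asks whether less CD44 changes the response. PI15 went from 22.9 ± 1.99 to 13.3 ± 1.73 CPM with the drug in control cells and from 13.5 ± 0.52 to 3.63 ± 0.75 CPM in knockdown cells, and EHF from 428 ± 16.5 to 347 ± 13.8 CPM and from 208 ± 4.63 to 102 ± 15.7 CPM (SD, n = 3). NOS2 went from 16.9 ± 0.62 to 6.10 ± 0.26 CPM in control cells and from 9.27 ± 0.24 to 6.29 ± 0.48 CPM in knockdown cells, and the exchange factor PLEKHG5 from 46.4 ± 2.79 to 30.1 ± 1.77 CPM and from 35.5 ± 2.42 to 34.8 ± 0.46 CPM (SD, n = 3). The log2 differences between the responses were -1.07 (SE 0.18) for PI15, -0.71 (SE 0.09) for EHF, 0.91 (SE 0.14) for NOS2 and 0.59 (SE 0.09) for PLEKHG5. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment these had adjusted p = 0.00657, 0.000730, 0.00505 and 0.00423. These 4 genes were picked with their calls under the alternatives known, so those calls are no test of how steady they are. They passed with the other edgeR scalings, filters, block and GC corrections and with each library left out. Only PI15 among them reached 2-fold, and none passed in the 3 limma fits to FPKM. Of the other genes that the rule gave, C1orf116 at 1.03, MSANTD3-TMEFF1 at -1.01 and PCDHB9 at -0.87 lost the call with the correction for GC content. DESeq2 adjusted p only over the 4505 genes with a mean count of at least 884, where EHF passed, and gave no adjusted p to PI15, NOS2 or PLEKHG5. Interferon-stimulated genes were the only list to shift, downward, with a median of -0.50 (interquartile range -0.77 to -0.29) and 2 called members over all genes, or 16 adjusted over the list alone. With the correction for GC content 0 members passed over all genes in edgeR, and 22 had an unadjusted p below 0.05. Limma camera gave this list adjusted p = 1.7e-12, and adjusted p = 0.999 with an estimated correlation, the call was also lost in fry, and the median was -0.33 without knockdown temozolomide 2.

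Over all genes, 135 passed the test of this difference, 56 above and 79 below 0, and 2279 had an unadjusted p below 0.05 in edgeR. Relative log expression size factors gave 45 and 107. The number was 35 with a correction for GC content, 53 with one for GC content and length, 372 in DESeq2 among those 4505 genes, 546 without the low-count filter and 0 in the limma fits to FPKM, where 1650, 1646 and 1982 genes had an unadjusted p below 0.05. Leaving out single libraries gave 22 without control DMSO 1, 272 without control DMSO 2, 25, 67 and 31 without knockdown DMSO 1, 2 and 3, 395, 19 and 28 without control temozolomide 1, 2 and 3, and 76 and 394 without knockdown temozolomide 1 and 3. The log2 differences correlated with GC content across genes (Spearman's rho 0.47), and PI15, EHF, NOS2 and PLEKHG5 passed with either correction. SOX2 at -0.12 (SE 0.05), MSH6 at -0.04 (SE 0.05), MKI67 at 0.09 (SE 0.05), CDKN1A at 0.11 (SE 0.08) and VIM at 0.13 (SE 0.04) did not pass (edgeR quasi-likelihood, Benjamini-Hochberg, adjusted p = 0.195, 0.678, 0.350, 0.550 and 0.118).

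**Figure D4:**
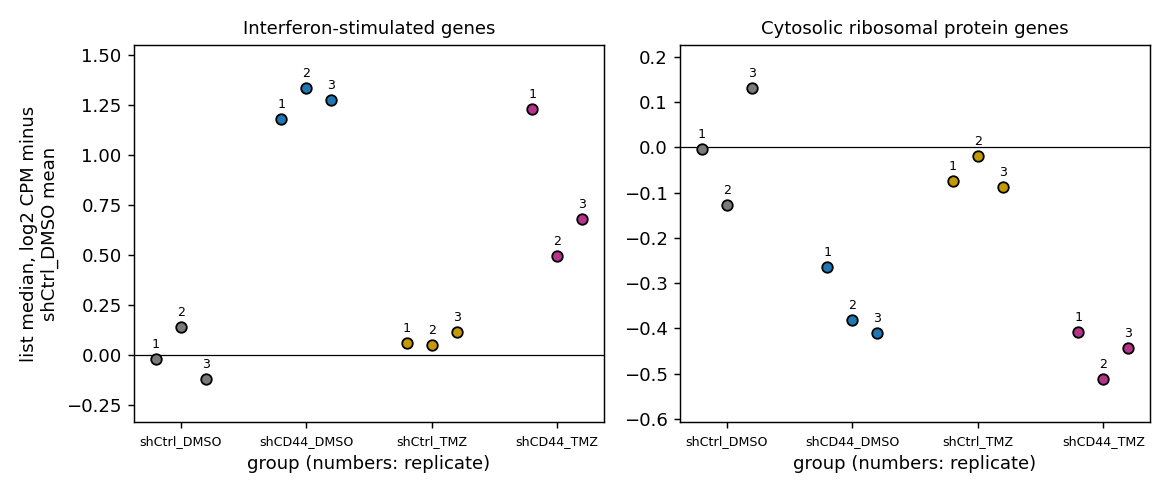
Median log2 deviation from the control DMSO mean of interferon-stimulated and ribosomal protein genes in each of the 12 libraries. For interferon-stimulated genes the knockdown DMSO libraries lie at 1.18, 1.33 and 1.27 and the knockdown temozolomide libraries at 1.23, 0.50 and 0.68.

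Of the 41 lists tested, 13 shifted in none of the 6 comparisons in limma camera with the preset correlation, with medians from -0.30 to 0.24 and a lowest limma camera adjusted p of 0.0508. Mismatch and alkylation repair genes were among them, with medians from -0.09 to 0.04, as were apoptosis genes, from -0.07 to 0.06, and G1/S genes, from -0.08 to 0.03. These lists are not shown to be unchanged. Limma's fry, which does not set a list against the other genes, called mismatch repair genes in 3 comparisons, apoptosis genes in 4 and G1/S genes in 3. Among the 13 it also called p53 targets in 3 comparisons, and WNT and Notch pathway genes in 5 each. With a correction for GC content camera called G1/S genes for knockdown under DMSO, with 9 rises, 21 falls and a median of -0.06. MSH6 in the mismatch repair list fell with knockdown in both comparisons, at -0.21 and -0.26.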

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

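Both tests of the GC trend in this part, and the view of splits by the number of libraries moved, were chosen only after the result was seen, while the splits themselves were planned. For 12 named genes and 1 list, the test of the difference between the temozolomide responses of knockdown and control cells passed its threshold. PI15 differed by -1.07, EHF by -0.71, NOS2 by 0.91 and PLEKHG5 by 0.59. C1orf116 differed by 1.03, MSANTD3-TMEFF1 by -1.01, PCDHB9 by -0.87, GAR1 by -0.67, UPP1 by 0.59, IFIH1 by -0.54, ANKHD1-EIF4EBP3 by 0.50 and SAMD9 by -0.48. Interferon-stimulated genes had a median of -0.50. In limma camera this list had adjusted p = 0.999 with an estimated correlation, and its call was also lost in fry.

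Of the 135 called genes, 94.1% lay on the side that their GC content predicts, and 106 were no longer called once a GC trend per library was removed. For those 106 the median size of the difference went from 0.30 to 0.19 and the median SE from 0.064 to 0.055, so over these genes the differences shrank. Of the named genes, MSANTD3-TMEFF1 (-0.86), SAMD9 (-0.34), IFIH1 (-0.49), C1orf116 (1.01), GAR1 (-0.66), PCDHB9 (-0.85) and UPP1 (0.59) lost the call, the last 4 with little change in size. A GC trend between libraries is therefore a candidate explanation for the 106 lost calls as a set. It is not one for C1orf116, GAR1, PCDHB9 and UPP1, whose differences stayed nearly as large, and why these lost the call was not tested. For the 29 genes that passed with the same sign after the correction, among them PI15, EHF, NOS2, PLEKHG5 and ANKHD1-EIF4EBP3, the trend is argued against as the whole cause. A different response of cells with less CD44 and an effect of the hairpin itself both stay open for them. No sample here separates these, so neither was tested.

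Of 100 splits of the libraries, 7 gave at least 135 genes, the real one included, and 93 gave at least 1 shifted list. The 6 other splits with as many genes point to a structure of the samples: they move unequal numbers of libraries between treatments in control and knockdown cells, so that part of the temozolomide effect enters the difference. The highest called 4603 genes and shifted 25 lists, with the treatment swapped in all 3 libraries of 1 knockdown state. These splits therefore do not decide whether chance can give 135 genes. In the 28 drawn splits that move as many libraries in both kinds of cells, edgeR called 0 genes, with 133 to 511 at an unadjusted p below 0.05 against 2279 in the real split. These splits keep part of the real difference and mix the treatments within their groups, which widens the spread, so they do not decide the number of genes either. Of the 28, 21 shifted at least 1 list of any kind, and up to 9. They do not decide the interferon list either, so the splits exclude chance for neither result.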

How the results depend on the processing

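The corrections for GC content, alone or with length, were chosen only after the results were seen, and the cause of the changes below was not tested. The difference between the temozolomide responses depended most on the processing, with 135 genes and 1 list. It gave 546 genes without the low-count filter, 372 in DESeq2 (of the 4505 genes to which it gave an adjusted p), 35 and 53 with the corrections for GC content and for GC content with length, 6 at 2-fold, 13 at an adjusted p below 0.01, and 0 in each of the 3 limma fits to FPKM, where 1650, 1646 and 1982 genes had an unadjusted p below 0.05. Its lists numbered 5 and 4 with those corrections, 0 in fry and 0 with an estimated correlation in limma camera (4 and 1 at an unadjusted p below 0.05). With the replicate number as a block, a pairing that the libraries do not clearly show, it gave 222 genes.

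At 2-fold the comparisons of 2 groups kept 458 genes (knockdown, DMSO), 427 (knockdown, temozolomide), 91 (temozolomide, control), 72 (temozolomide, knockdown) and 572 (both changes). An adjusted p below 0.01 left 2187 and 1578 genes for temozolomide in control and knockdown cells, and unfiltered FPKM 1875 for the latter. With an estimated correlation limma camera shifted 0, 0, 1, 4 and 0 lists in the same order (8, 6, 12, 17 and 8 at an unadjusted p below 0.05), so list calls rest on the preset correlation. Fry shifted 33, 31, 28 and 36 lists for knockdown under DMSO and temozolomide, temozolomide in control cells and both changes. Unlike camera, fry does not set a list against the other genes, so its numbers are not alike in meaning. In these comparisons 42.6%, 42.3%, 27.5% and 49.9% of all tested genes were called in edgeR.

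The correlation of the knockdown effects was 0.32 in DESeq2, 0.26 without the filter and 0.80, 0.78 and 0.78 in the fits to FPKM, and that of the temozolomide effects 0.12, 0.094, 0.56, 0.51 and 0.52. Signs turned for MSH6 with temozolomide in control cells (-0.00165, GC content) and in the difference (0.036 with GC content, 0.030 with length added), for MKI67 with knockdown under temozolomide (0.00526 with library totals alone; 0.00240, 0.00241 and 0.00240 in the fits to FPKM), and for both changes in VIM (0.00109 with library totals alone, 0.00138 in each of the 3 fits to FPKM), PDIA3 (0.000539, library totals alone) and PPAT (-0.00352, GC content and length).

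Leaving out 1 library at a time gave 4621 to 5228 genes for knockdown under DMSO, 4686 to 5079 under temozolomide, 2680 to 3395 and 2095 to 2415 for temozolomide in control and knockdown cells, 5678 to 6137 for both changes, and 19 (without control temozolomide 2) to 395 (without control temozolomide 1) for the difference. Lists numbered 13 to 16, 14 to 16, 17 to 19, 19 to 24, 13 to 18 and 1 to 6. CD44 ran from -1.41 to -1.35 and from -1.35 to -1.31, and the correlations from 0.64 to 0.69 and from 0.30 to 0.39. CDKN1A with knockdown under DMSO ran from -0.034 to 0.042 and MKI67 with temozolomide in knockdown cells from -0.015 to 0.033, each negative without knockdown DMSO 1. Of 13184 settings over 730 gene results, 12642 kept direction and call, 513 lost the call, 14 gained it and 15 turned. Of 1150 over the 88 list results called in the main analysis, 1013 kept both and 137 lost the call, 83 of them with an estimated correlation. Lists without a main call were left out of this count, so it could not show a gained call. At this depth MGMT, with a floor of 0.121 to 0.222 CPM, could not be measured.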

Other observations

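The tests of GC content with length, of GC content for the interferon difference, of the spread between libraries, of the hairpin or vector, and of CD44 length were chosen only after the result was seen, and the other tests and the splits were planned.

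Of 20 listed epithelial markers, 10 passed the low-count filter over all libraries. Their levels in control DMSO libraries differed widely, with KRT5 at 833 ± 18.9 CPM, KRT14 at 259 ± 10.5 CPM, CLDN4 at 45.8 ± 1.44 CPM and OCLN at 7.81 ± 1.36 CPM. EHF, which is not on that list, was at 428 ± 16.5 CPM and the glial progenitor factor SOX2 at 389.9 ± 6.86 CPM (SD, n = 3).

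Ribosomal protein genes were lower with knockdown under DMSO. A trend with GC content and annotated length is argued against, since the list median was -0.32 after both were removed. A shift of abundant transcripts is argued against by 250 other genes matched on annotated length, GC content and level, with a median of -0.078. These lengths are those of the longest annotated transcript, at a median log2 length of 10.9 for ribosomal protein and 11.1 for matched genes. Neither test covers transcripts expressed at a shorter length, so a shift of short transcripts stays open. Of 72 members, 61 had estimated counts with no fraction in any library (tolerance 0, in values with 2 decimals), and their median was -0.36. This argues against reads divided with other genes of the counting reference. Reads from pseudogenes missing from that reference would be counted whole. The annotation is not given, so this test does not decide on pseudogenes. Scaling by library totals alone left -0.32. An effect of less CD44 and an effect of the hairpin itself both stay open, and no sample here separates them, so neither was tested.

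Interferon-stimulated genes were higher with knockdown, and less so under temozolomide. Control cells mixed into the knockdown temozolomide libraries are argued against, since the 44.1% needed would bring CD44 to -0.61, where -1.33 (SE 0.03) was measured. For the smaller rise, the spread between libraries stays open: the list medians were 1.23, 0.50 and 0.68 in those libraries. An exact permutation of the library medians gave p = 0.065, where 0.005 is the smallest possible. It redrew the treatment within each kind of cell, also in unequal numbers. This p therefore supposes no temozolomide effect in either kind of cell, and not an equal effect in both. With 1 hairpin, a response to the hairpin or its vector cannot be told apart from the loss of CD44 for the rise of 1.28 under DMSO, since the design gives both the same samples. A GC trend is argued against for the difference, which was -0.46 after correction.

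CD44 FPKM fell more than CD44 counts, and the transcript length this implies changed more than in 98.9% of 10372 genes under DMSO. This length is the ratio of the same counts and FPKM, so the value restates the observation and does not test whether the CD44 transcripts left differ in length from those lost, which stays open.

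Each comparison of 2 groups has 10 splits of its 6 libraries, too few for a share under 0.05, and in each the real split was the 1 with the highest count. For knockdown under DMSO and temozolomide, temozolomide in control and knockdown cells, and both changes, the real splits called 5458, 5426, 3529, 2854 and 6398 genes and the highest others 0, 0, 0, 1 and 0 in edgeR (at most 896, 901, 1173, 709 and 934 at an unadjusted p below 0.05). The real splits shifted 16, 16, 17, 24 and 14 lists and the highest others 11, 12, 16, 20 and 8 in limma camera. Each other split sets 2 libraries of one group and 1 of the other against the reverse. It therefore keeps part of the real difference and widens the spread within its groups, so these splits decide neither number. Still, with at most 1 gene called, limma camera with the preset correlation shifted up to 20 lists in them. A list call with that preset therefore does not by itself show that the genes of the list changed.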
